A study of Pagiophloeus tsushimanus with 15 samples.

How the data were processed

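RNA was sequenced from whole larvae of Pagiophloeus tsushimanus. Per the labels, total RNA was extracted with TRIzol and libraries were made with NEBNext Ultra reagents. The 15 libraries were grouped by diet, with 3 libraries in each of 5 groups, taken from the treatment field, with the replicate number from the titles: a diet without terpenoids, the additive labelled EO at 10 or 30 mg/g, and D-camphor at 17 or 41 mg/g. The deposited table holds 1 column per library, headed by a letter and a replicate number, and these were matched to the libraries by the letter and replicate number in the titles. The aligner, the assembler, the counting method and any build are not given in the sources used here. Whether replicates are separate animals, pools or repeat preparations is not stated either.

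The deposited values are TPM, which the authors normalised by transcript length and scaled to an equal total per library, with 2 decimals, for 34486 unigenes. The columns were checked to sum to between 999999.16 and 1000001.21. Of the unigenes, 18488 carry a protein description and 15998 do not, and 34 are listed at 0 in all libraries. TPM holds no read counts, so the depth per library and the counting precision it gives are unknown, and the smallest step in the table is 0.01 TPM. Every column was used. No genome of this species was used, so unigenes are named by their identifier and the description in the table, which gives a similar protein in another species and not a measured function.

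TPM was transformed to log2(TPM + 1). Unigenes with a mean of at least 1 TPM over all libraries were tested, 12510 in number, of which 9125 are described. A linear model with 1 mean per group was fitted to all 15 libraries in limma 3.58.1 under R 4.3.3, with a trend of the variance on the mean. It has 10 residual degrees of freedom and 2.12 prior degrees of freedom. Tests were two-sided moderated t tests, and p-values were adjusted by the Benjamini-Hochberg method over the unigenes of each comparison, with 0.05 as the threshold. A call is a unigene past this threshold. The comparisons were each diet against untreated, the mean of the 4 terpenoid diets against untreated, the higher against the lower dose of each additive, EO against D-camphor at the lower and at the higher doses, the difference between the dose steps of the additives, and an F test of any difference. Comparisons, thresholds, gene list names and the naming rule were set before the data were examined.

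Named unigenes follow a rule. In each comparison with untreated larvae it takes the 10 called unigenes with the largest rise and the 10 with the largest fall whose 3 treated values lie on the same side of all 3 untreated values, and up to 4 called members of each gene list with the largest change. Unigenes named outside this rule are marked as chosen after their values were seen.

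Gene lists were tested for 24 classes: cytochrome P450, glutathione S-transferase, UDP-glycosyltransferase, carboxylesterase, ABC transporter, sulfotransferase and epoxide hydrolase, cuticle protein, chitin metabolism, heat shock protein, antioxidant, digestive protease, plant cell wall degradation, chemosensory, moulting and juvenile hormone, lipid metabolism, oxidative phosphorylation, cytosolic ribosomal protein, immune, fat body, muscle, haemocyte, nervous system, germ line and other organisms. Members were found by words in the descriptions, and these search words were written after the table had been seen. Lists with at least 5 tested members were tested by camera with a preset correlation of 0.01 between members, and 190 tests over 10 comparisons were adjusted together. Alternatives were camera with the correlation estimated from the data and fry. List members were also adjusted over their list alone.

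Single values per library were compared by exact permutation tests. The overlap and correlation of fold changes that share the untreated libraries were set beside 100 simulated data sets without a diet effect. The alternatives were a pseudocount of 0.1, no filter, a filter at 5 TPM, median-of-ratios scaling of the TPM values, a block for the replicate number, array quality weights, a fit to the groups compared alone, and leaving out each library in turn. After the data had been seen, 2 more were added: leaving out together the 3 libraries highest on the first principal component, and the mean cuticle protein level as a covariate. The groups of 3 were also split in all other ways, or in 100 drawn ways where there were more.

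The method was tested on simulated data with each unigene's mean level over all 15 libraries and its residual spread around the group means. Changes were placed in the libraries of EO at 30 mg/g, with 50 changed unigenes at each size. Values were drawn independently, so the simulation lacks any structure that unigenes share within a library, and recovery in the real data may differ. Against untreated larvae, the method recovered 58% of the unigenes changed 2-fold, 90% at 4-fold, 96% at 16-fold and 100% at 64-fold. It called 8 unchanged unigenes.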

Results

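Transcript levels were measured by RNA sequencing in whole bodies of larvae of the weevil Pagiophloeus tsushimanus, a beetle described in the series title as an emerging insect pest. The 15 libraries form 5 groups of 3: larvae on a diet without terpenoids (untreated), on a diet with the additive labelled EO at 10 mg/g or 30 mg/g, and on a diet with D-camphor at 17 mg/g or 41 mg/g. D-camphor is a volatile monoterpenoid ketone of plants. The question, as the series labels give it, is how larvae on a terpenoid diet differ from larvae on a terpenoid-free one, with metabolic and cuticular resistance named in the title. Values are in TPM, a length-normalised unit of transcript abundance, for 34486 assembled unigenes, of which 18488 carry a protein description with the species of the matched protein. TPM keeps no read depth, so the depth of each library is unknown, and no counting interval is given. Between 11478 and 13659 unigenes lay over 1 TPM in a library, and the 10 most abundant unigenes held 18.5% to 24.7% of the TPM. No 2 libraries were identical, and the median correlation between libraries was 0.947 within groups and 0.934 between groups. The labels do not say whether the 3 replicates of a group were separate animals or pools. The limma, fry and exact permutation p-values below therefore measure only the spread between these libraries. Camera sets list members against the other unigenes, and Fisher's exact test counts unigenes. Their p-values do not measure that spread, and small ones are no evidence of replication over libraries.

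On EO at 10 mg/g, 4 unigenes described as cytochrome P450 family 6 members, monooxygenases of a family that oxidises foreign compounds in insects, were higher than in untreated larvae. The unigene described as probable cytochrome P450 6a20 (TRINITY_DN12993_c0_g1) was listed at 0, 0 and 1.28 TPM in untreated larvae and at 171 ± 149 TPM (SD, n = 3) on EO at 10 mg/g, a log2 fold change of 6.70 (SE 0.51, adjusted p = 9.15e-05 by limma; 9.14 with a pseudocount of 0.1, since 2 untreated values are 0). Of the unigenes described as cytochrome P450 6a2-like, TRINITY_DN9219_c0_g1 rose from 1.27 ± 0.535 to 67.6 ± 19 TPM (log2 fold change 4.91, SE 0.29, adjusted p = 8.7e-06) and TRINITY_DN32261_c0_g1 rose from 0.727 ± 0.376 to 72.1 ± 57.1 TPM (5.16, SE 0.57, adjusted p = 0.00311). Probable cytochrome P450 6a14 (TRINITY_DN1085_c0_g1) rose from 34.6 ± 12.9 to 226 ± 126 TPM (2.60, SE 0.35, adjusted p = 0.0138). The remaining rises were in TRINITY_DN986_c0_g1 and TRINITY_DN1904_c0_g1, both described only as unknown proteins of the bark beetle Dendroctonus ponderosae, by log2 fold changes of 4.54 and 2.68.

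The unigenes that fell on EO at 10 mg/g were all at low levels. TRINITY_DN43302_c0_g1, which has no description, fell by 1.86 on the log2 scale from 4.03 ± 1.12 to 0.367 ± 0.0252 TPM, and a unigene described as elongation factor 1-alpha of the priapulid worm Priapulus caudatus (TRINITY_DN1422_c0_g1) fell by 1.64 from 3.33 ± 0.64 to 0.4 ± 0.338 TPM. A unigene described as harmonin, a scaffold protein (TRINITY_DN2749_c0_g1), fell by 0.75 from 7.65 ± 0.967 to 4.14 ± 0.488 TPM. The means of all 3 were also below untreated larvae on the other diets. On EO at 30 mg/g and D-camphor at 17 and 41 mg/g, TRINITY_DN43302_c0_g1 stood at 1.16, 0.63 and 0.813 TPM. TRINITY_DN1422_c0_g1 stood at 0.573, 0.763 and 0.497 TPM, and TRINITY_DN2749_c0_g1 at 5.64, 5.03 and 5.21 TPM. Of these, only TRINITY_DN1422_c0_g1 on EO at 30 mg/g was called. In total, limma called 9 of the 12510 tested unigenes on EO at 10 mg/g, 6 higher and 3 lower, of which 8 changed at least 2-fold. An unadjusted p under 0.05 was found for 789 (6.31%), where chance alone gives 5% on average. Unigenes vary together within libraries, so in any 1 comparison this share can lie well off 5% by chance. In all 9 the 3 treated values lay on one side of the 3 untreated ones. Chance gives this separation for 10% of unselected unigenes. The 9 were picked by their p-value on the same values, so their separation adds no support. The 3 falls were called in 2, 4 and 2 of the 15 refits that each leave out 1 library. The calls of TRINITY_DN1085_c0_g1 and TRINITY_DN1904_c0_g1 were lost without untreated replicate 1 or untreated replicate 2. The count was 4 without untreated replicate 2. The median log2 fold change of all tested unigenes was -0.122, and scaling by median of ratios moved it by 0.119 and ended the call of TRINITY_DN43302_c0_g1 (adjusted p = 0.0987). With a pseudocount of 0.1 the calls of TRINITY_DN43302_c0_g1 (log2 fold change -3.11, adjusted p = 0.151) and TRINITY_DN1422_c0_g1 (-2.96, adjusted p = 0.211) ended. A filter at 5 TPM ended that of TRINITY_DN2749_c0_g1 (adjusted p = 0.0635). Leaving out the 3 libraries highest on the first principal component, described from here on as those that lie apart on it, ended all 3 (adjusted p = 0.242 for each).

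On EO at 30 mg/g the same 4 P450 unigenes reached their highest group means. Probable P450 6a20 (TRINITY_DN12993_c0_g1) stood at 751 ± 163 TPM (log2 fold change 9.13, SE 0.51, adjusted p = 2.59e-06), and probable P450 6a14 (TRINITY_DN1085_c0_g1) at 938 ± 198 TPM (4.76, SE 0.35, adjusted p = 2.29e-05). The P450 6a2-like unigenes TRINITY_DN9219_c0_g1 and TRINITY_DN32261_c0_g1 stood at 556 ± 144 and 194 ± 70.7 TPM, with log2 fold changes of 7.93 and 6.78. TRINITY_DN1820_c1_g1, described as juvenile hormone epoxide hydrolase 1-like, an enzyme of a family that opens the epoxide ring of the insect juvenile hormone, rose from 42 ± 12.9 to 239 ± 37.1 TPM (2.51, SE 0.35, adjusted p = 0.0145). The 4 P450 unigenes kept their calls in all 15 refits that leave out 1 library, with adjusted p up to 4.88e-05, 8.83e-07, 0.00134 and 0.00033 for TRINITY_DN12993_c0_g1, TRINITY_DN9219_c0_g1, TRINITY_DN32261_c0_g1 and TRINITY_DN1085_c0_g1.

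**Figure D1:**
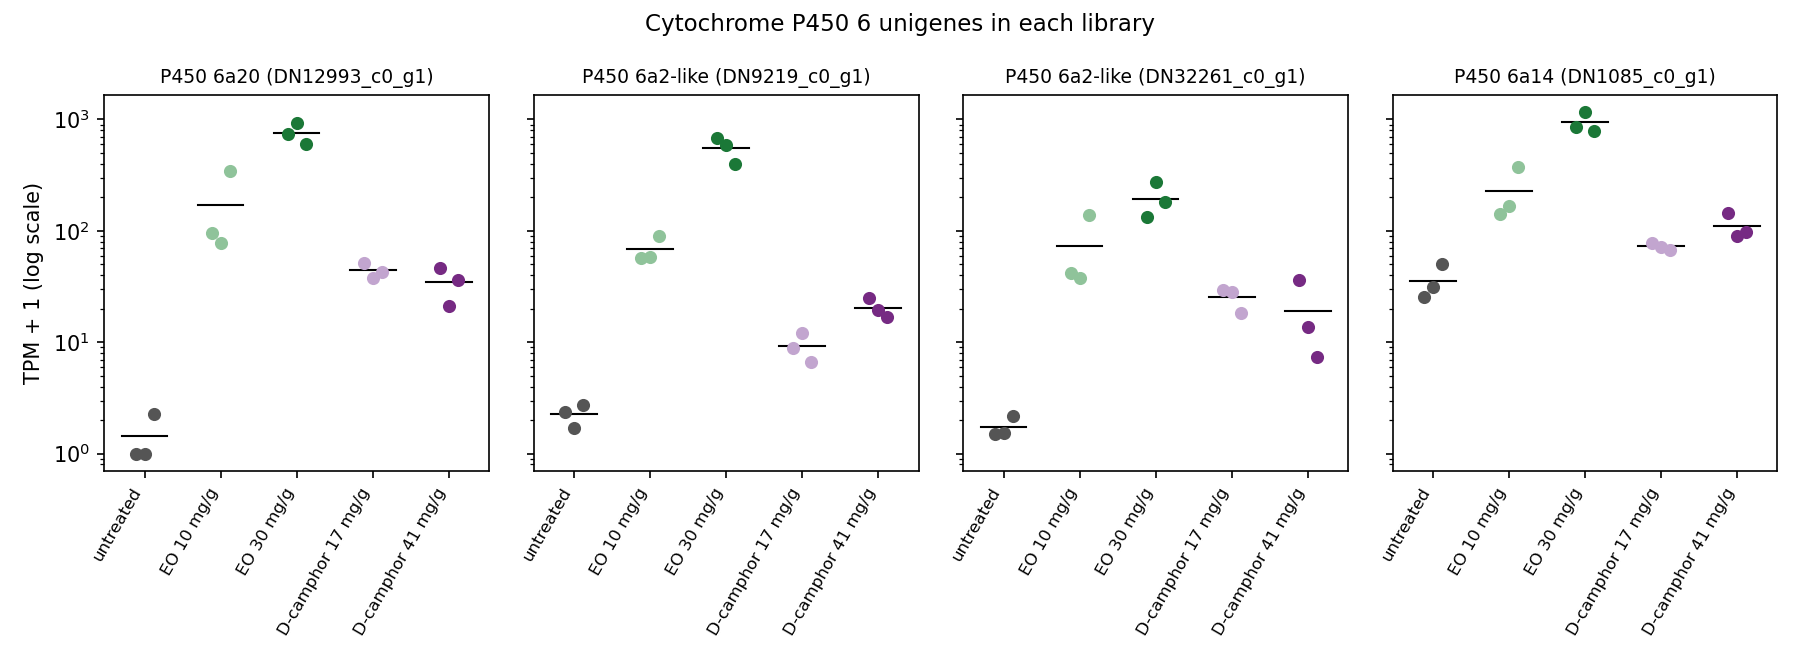
TPM plus 1, on a log axis, of 4 cytochrome P450 family 6 unigenes in each of the 15 libraries. Points are single libraries (n = 3 per group), horizontal lines are the group mean TPM plus 1, and the means on EO 30 mg/g (751, 556, 194 and 938 TPM from left to right) are the highest in each panel.

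Most other rises on EO at 30 mg/g were in unigenes of unknown function. TRINITY_DN986_c0_g1 rose from 35.3 ± 11 to 1710 ± 164 TPM (log2 fold change 5.59), TRINITY_DN1904_c0_g1 from 33.7 ± 9.1 to 957 ± 174 TPM (4.80) and TRINITY_DN986_c0_g2 from 657 ± 110 to 3010 ± 416 TPM (2.20). The TPM of TRINITY_DN1085_c0_g1 was 0.771 to 1.16 times that of TRINITY_DN1904_c0_g1 in all 15 libraries, so the levels of this pair, one a P450 and the other an unknown protein, are uncertain where they share reads. TRINITY_DN1113_c0_g2 rose from 326 ± 108 to 3000 ± 1040 TPM (3.19) and TRINITY_DN1224_c0_g1 from 22.5 ± 3.71 to 126 ± 8.41 TPM (2.44), both described as uncharacterized weevil or bark beetle proteins. The 3 called unigenes that the naming rule left out, named here after their values were seen, were TRINITY_DN7369_c0_g1 (hypothetical protein, 1.34), TRINITY_DN2305_c0_g1 (hypothetical protein, 1.18) and TRINITY_DN7344_c0_g1 (venom acid phosphatase Acph-1-like, 0.97).

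Among the 10 unigenes that fell on EO at 30 mg/g, 5 were described as the uncharacterized proteins LOC109542840, LOC109542841 or LOC109542842 of Dendroctonus ponderosae, and most of them were abundant. TRINITY_DN7259_c1_g1 fell by 1.87 on the log2 scale from 3080 ± 993 to 815 ± 122 TPM, TRINITY_DN21725_c0_g1 by 1.58, TRINITY_DN20567_c0_g1 by 1.51, TRINITY_DN34445_c1_g1 by 1.27 and TRINITY_DN7446_c0_g2 by 1.10. TRINITY_DN38693_c0_g1 and TRINITY_DN37860_c0_g1, unknown proteins of the same species, fell by 1.66, from 26500 ± 8680 to 8240 ± 1520 TPM, and by 1.41, from 5000 ± 1210 to 1860 ± 291 TPM. A mucin-2-like unigene (TRINITY_DN270_c0_g1), from a family of secreted glycoproteins, fell by 1.49 from 14.8 ± 5.71 to 4.55 ± 1.5 TPM. The last 2 falls were in low-level unigenes described from animals other than beetles, a hexose transporter HXT13-like unigene (TRINITY_DN750_c0_g1, 4.14 ± 1.8 to 0.34 ± 0.35 TPM, log2 fold change -1.91) and TRINITY_DN1422_c0_g1 (-1.46). Both were low on every terpenoid diet and highest in untreated larvae. TRINITY_DN750_c0_g1 lay at 2.37 to 5.96 TPM in untreated larvae and 0 to 1.38 TPM in the 12 terpenoid libraries. TRINITY_DN1422_c0_g1 lay at 2.7 to 3.98 and 0.18 to 1.07 TPM.

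**Figure D2:**
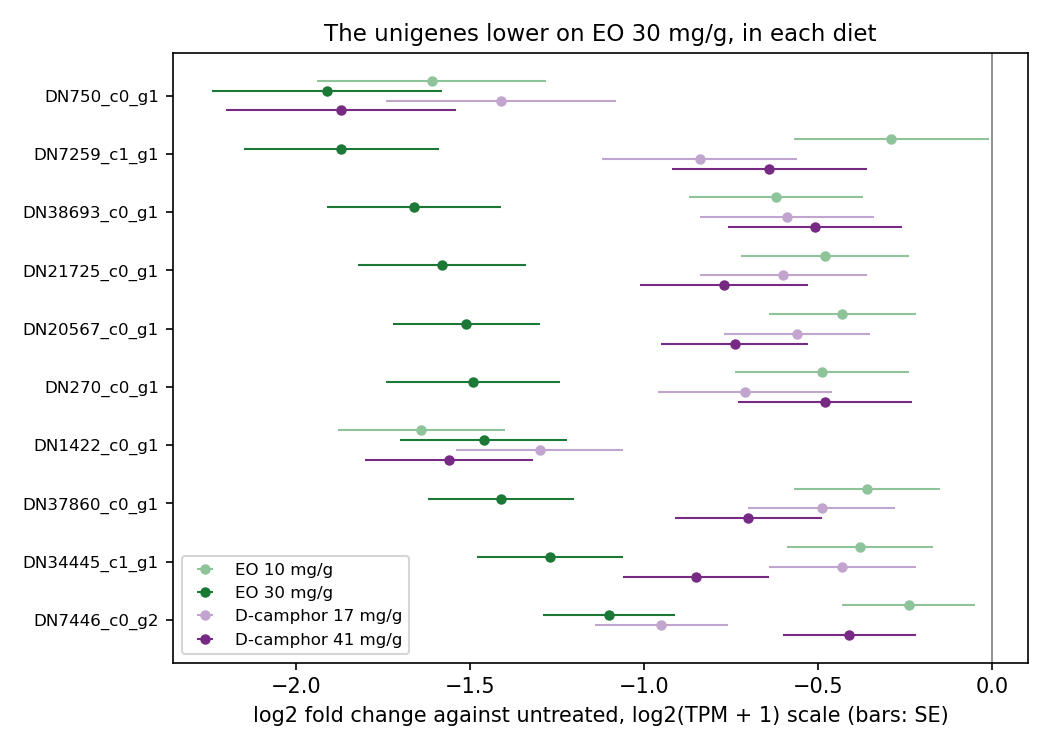
Log2 fold change against untreated, on the log2(TPM + 1) scale, of the 10 unigenes that fell on EO at 30 mg/g, in each of the 4 terpenoid diets. Points are limma estimates and bars are their standard errors, and all 10 estimates for EO 30 mg/g lie between -1.91 and -1.10.

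In total, limma called 23 unigenes on EO at 30 mg/g, 13 higher and 10 lower, of which 22 changed at least 2-fold. For 1101 (8.8%) the unadjusted p was under 0.05. All 10 falls lost their call under median-of-ratios scaling, which called 13 higher and 0 lower unigenes by limma, with adjusted p of the 10 between 0.0512 and 0.178 and log2 fold changes between -1.86 and -1.04. The count was 8 without untreated replicate 2, 10 without EO 30 mg/g replicate 1, 8 without EO 30 mg/g replicate 2 and 13 without D-camphor 17 mg/g replicate 2. Without EO 10 mg/g replicate 1, EO 30 mg/g replicate 1 and D-camphor 41 mg/g replicate 2 together, which lie apart on the first principal component, 21 were called on EO at 30 mg/g, of which 11 were among the 23 and none was 1 of the 10 falls. The rise of TRINITY_DN1224_c0_g1 lost its call with scaling (adjusted p = 0.0512). The rises of TRINITY_DN1113_c0_g2, TRINITY_DN1820_c1_g1 and TRINITY_DN1224_c0_g1 were called in 9, 11 and 4 of the 15 refits that leave out 1 library, against 1 to 12 for the falls. With a pseudocount of 0.1 the falls of TRINITY_DN750_c0_g1 (log2 fold change -3.62, adjusted p = 0.146) and TRINITY_DN1422_c0_g1 (-2.37, adjusted p = 0.22) lost their calls. Without a filter the calls of TRINITY_DN38693_c0_g1 (adjusted p = 0.0504) and TRINITY_DN34445_c1_g1 (adjusted p = 0.0536) ended.

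On D-camphor at 17 mg/g, 3 of the same P450 unigenes were higher than in untreated larvae. Probable P450 6a20 (TRINITY_DN12993_c0_g1) stood at 43.2 ± 7.13 TPM (log2 fold change 5.06, SE 0.51, adjusted p = 0.00433 by limma). The 6a2-like unigenes TRINITY_DN32261_c0_g1 and TRINITY_DN9219_c0_g1 stood at 24.4 ± 6.12 and 8.18 ± 2.72 TPM, with log2 fold changes of 3.87 and 2.0 and an adjusted p = 0.0473 for each. TRINITY_DN986_c0_g1 rose by 2.55 to 208 ± 38.4 TPM, and TRINITY_DN7034_c0_g1, described as an uncharacterized protein, rose by 4.60 from 3.23 ± 0.483 to 109 ± 46.7 TPM. Limma called 5 unigenes, all higher and all changed at least 2-fold, and 781 (6.24%) had an unadjusted p under 0.05. In all 5, the values of the groups did not overlap, which chance gives for 10% of unselected unigenes. As the 5 were picked by their p-value on these values, this adds no support.

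The call of TRINITY_DN12993_c0_g1 on D-camphor at 17 mg/g held in all 15 refits that leave out 1 library, with an adjusted p up to 0.0476, while the other 4 calls held in 3 or 4 of the 15. The count was 8 without EO 10 mg/g replicate 1, 3 without EO 30 mg/g replicate 3 or either of D-camphor 41 mg/g replicates 1 and 2, 2 without untreated replicate 1, EO 30 mg/g replicate 1 or D-camphor 17 mg/g replicate 2, and 1 without untreated replicate 2, EO 10 mg/g replicate 2, EO 30 mg/g replicate 2 or either of D-camphor 17 mg/g replicates 1 and 3. Median-of-ratios scaling called 6 higher and 1 lower unigenes. Without the 3 libraries that lie apart on the first principal component, TRINITY_DN32261_c0_g1 and TRINITY_DN9219_c0_g1 lost their calls (adjusted p = 0.102 and 0.087).

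On D-camphor at 41 mg/g, limma called 2 unigenes, both of them P450s and both higher. Probable P450 6a20 (TRINITY_DN12993_c0_g1) stood at 33.6 ± 12.6 TPM (log2 fold change 4.64, SE 0.51, adjusted p = 0.00541) and the 6a2-like TRINITY_DN9219_c0_g1 at 19.5 ± 3.97 TPM (3.18, SE 0.29, adjusted p = 0.00125). TRINITY_DN32261_c0_g1 had a log2 fold change of 3.17 with an adjusted p = 0.11, and TRINITY_DN986_c0_g1 one of 2.50 with an adjusted p = 0.0564. Both called unigenes changed at least 2-fold with groups that did not overlap, and 781 unigenes (6.24%) had an unadjusted p under 0.05. TRINITY_DN9219_c0_g1 was called in all 15 refits that leave out 1 library, and TRINITY_DN12993_c0_g1 lost its call without untreated replicate 1 or D-camphor 41 mg/g replicate 3 (adjusted p up to 0.056). The count was 1 in each of those refits, 7 and 9 without untreated replicates 2 and 3, 4 and 5 without EO 10 mg/g replicates 1 and 3, and 11 without D-camphor 41 mg/g replicate 1. Median-of-ratios scaling called 5 unigenes.

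The mean of the 4 terpenoid diets against untreated larvae had 769 unigenes (6.15%) at an unadjusted p under 0.05. It gave 11 calls by limma, 8 higher and 3 lower, 10 of them at least 2-fold. The count was 7 without untreated replicate 2, 19 without untreated replicate 3 and 26 without EO 10 mg/g replicate 1, and median-of-ratios scaling called 13 higher and 4 lower. The 6 unigenes that rose on EO at 10 mg/g all rose on EO at 30 mg/g, against 0.00624 for independent lists. In the simulated data sets the mean number shared was 0. These hold no diet effect, with residuals shuffled over all libraries, so that 0 cannot tell a shared effect from shared controls. The 5 rises on D-camphor at 17 mg/g shared 4 with each dose of EO and 2 with D-camphor at 41 mg/g, and both rises on D-camphor at 41 mg/g were among those on each dose of EO. Across unigenes, which are not independent replicates, the fold changes of the 2 EO doses had a correlation of 0.77 and a covariance of 0.202, against 0.5 and 0.0994 simulated (a 95% range of 0.0095 to 0.246 for the covariance over 100 simulations). For EO at 30 mg/g and D-camphor at 41 mg/g the correlation was 0.48 and the covariance 0.148, against 0.5 and 0.0958 simulated. All 6 correlations between diets lie inside their simulated 95% ranges, as do 5 of the 6 covariances, so they do not separate a shared effect from shared controls. The exception is EO at 30 mg/g with D-camphor at 17 mg/g, with a covariance of 0.221 against 0.0111 to 0.215.

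Between the 2 doses of EO, 1 unigene passed the test. The P450 6a2-like TRINITY_DN9219_c0_g1 was 3.02 log2 units higher at 30 mg/g than at 10 mg/g (SE 0.29, adjusted p = 0.00223 by limma), with 3 of 3 libraries above all libraries of the lower dose. The other 3 P450 unigenes had log2 differences of 2.44 (TRINITY_DN12993_c0_g1, 95% interval 1.33 to 3.54, adjusted p = 0.338), 2.16 (TRINITY_DN1085_c0_g1, 1.41 to 2.91, adjusted p = 0.151) and 1.62 (TRINITY_DN32261_c0_g1, 0.38 to 2.87, adjusted p = 0.952). Of the unigenes called against untreated larvae at either dose, 6 rose at both, 1 fell at both, 2 were called at the lower dose alone and 16 at the higher dose alone, and 1 of all 25 was called between the doses. An unadjusted p under 0.05 was found for 622 unigenes, 4.97% of those tested, near the 5% that chance gives on average. The call was lost without EO 10 mg/g replicate 1, EO 30 mg/g replicate 1 and D-camphor 41 mg/g replicate 2 together, and 5 were called without EO 10 mg/g replicate 3.

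Between the 2 doses of D-camphor, limma called 0 unigenes, with 1190 (9.51%) at an unadjusted p under 0.05. The P450 6a2-like TRINITY_DN9219_c0_g1 had a log2 difference of 1.18 (SE 0.29, 95% interval 0.56 to 1.80, adjusted p = 0.253), and probable P450 6a20 (TRINITY_DN12993_c0_g1) one of -0.41 (SE 0.51, 95% interval -1.52 to 0.69, adjusted p = 0.859). Of the 5 unigenes called at either dose of D-camphor, 2 rose at both and 3 were called at the lower dose alone. Array quality weights in limma called 46, the fit without a filter on low values called 10, and the fit to these 2 groups alone called 16. The count was 9 without D-camphor 41 mg/g replicate 1, 4 without untreated replicate 2 or EO 10 mg/g replicate 1, 2 without untreated replicate 1 and 1 without D-camphor 17 mg/g replicate 1.

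The additives were also compared with each other at their lower and at their higher dose, and these doses differ in mg/g. At the lower doses (EO at 10 mg/g, D-camphor at 17 mg/g) the P450 6a2-like TRINITY_DN9219_c0_g1 was 2.91 log2 units higher on EO (SE 0.29, adjusted p = 0.00331 by limma). It was the only call, and 1250 unigenes (9.99%) had an unadjusted p under 0.05. Probable P450 6a20 (TRINITY_DN12993_c0_g1) had a log2 difference of 1.64 there, with a 95% interval of 0.54 to 2.75 and an adjusted p = 0.35. Camera set the P450 list higher on EO (adjusted p = 0.0449; adjusted p = 0.536 with an estimated correlation), while its median was -0.12, or 0.05 with scaling, and its mean was 0.05. The count of calls was 2 without EO 30 mg/g replicate 2 and 0 without the 3 libraries that lie apart on the first principal component. The median over all tested unigenes was -0.148 in this comparison and moved by 0.15 with scaling.

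At the higher doses (EO at 30 mg/g, D-camphor at 41 mg/g) all 4 P450 unigenes were higher on EO. The log2 differences were 4.75 for TRINITY_DN9219_c0_g1 (SE 0.29, adjusted p = 1.29e-05), 4.49 for TRINITY_DN12993_c0_g1, 3.61 for TRINITY_DN32261_c0_g1 and 3.09 for TRINITY_DN1085_c0_g1. The unknown proteins TRINITY_DN986_c0_g1, TRINITY_DN1904_c0_g1 and TRINITY_DN986_c0_g2 were higher on EO by 3.10, 3.04 and 1.87. Higher on EO as well, and named after their values were seen, were TRINITY_DN5695_c0_g1 (2.17), TRINITY_DN2305_c0_g1 (1.53) and TRINITY_DN154_c0_g2 (1.23), while TRINITY_DN16997_c0_g1 (early nodulin-75, -2.38), TRINITY_DN1624_c0_g1 (-1.29) and TRINITY_DN2083_c0_g1 (-0.97) were lower. Limma called 13 unigenes, 10 higher and 3 lower on EO, 12 of them at least 2-fold. For 1381 (11%) the unadjusted p was under 0.05. Median-of-ratios scaling called 12 higher and 6 lower, the count was 21 without D-camphor 41 mg/g replicate 1, and 3 were called without the 3 libraries that lie apart on the first principal component.

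Among the 24 gene lists, cytochrome P450 is the one with called members in every comparison with untreated larvae. Of its 38 tested members, 4, 4, 3 and 2 rose on EO at 10 and 30 mg/g and D-camphor at 17 and 41 mg/g, and 4, 7, 3 and 4 rose when adjusted over the list alone. The median log2 fold changes of the list were 0.02, 0.19, 0.16 and 0.05 (0.17, 0.24, 0.13 and 0.09 with median-of-ratios scaling), since the rise rests on few members, and the remaining members did not pass the test over all unigenes. The list was called by camera with a preset correlation in each of these comparisons (adjusted p = 7.52e-05, 8.37e-06, 0.0139 and 0.0171), and lost the call in each with an estimated correlation (adjusted p = 0.289, 0.289, 0.499 and 0.501 with an estimated correlation). In EO at 30 mg/g it was the list that fry, which tests whether members move one way on balance, called among 190 tests of lists (adjusted p = 0.00931).

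Cuticle protein unigenes, which encode structural proteins of the insect cuticle, mostly had higher estimates on the terpenoid diets, with a wide spread between replicates. Of the 56 tested members, 51, 51, 42 and 53 lay above 0 on EO at 10 and 30 mg/g and D-camphor at 17 and 41 mg/g, with median log2 fold changes of 1.65, 1.58, 0.87 and 3.26. No member was called by limma in these comparisons, and adjusted over the list alone 1 was called, on D-camphor at 41 mg/g. The mean log2(TPM + 1) over the members was 2.77 ± 0.39 in untreated larvae, 4.33 ± 2.59 and 4.56 ± 2.01 on EO at 10 and 30 mg/g, and 4.23 ± 0.6 and 5.83 ± 1.36 on D-camphor at 17 and 41 mg/g (SD, n = 3). It was 7.25 in EO 10 mg/g replicate 1, 6.87 in EO 30 mg/g replicate 1 and 7.23 in D-camphor 41 mg/g replicate 2, the 3 libraries that lie apart on the first principal component, which holds 23.5% of the variance. They are the highest on it, at 57.7, 53.7 and 33.7, while untreated replicate 2 lies at -36.4. Without these 3 libraries the medians were 0.2, 0.4, 0.87 and 2.35. All 3 are terpenoid libraries with the highest cuticle means, so leaving them out was bound to lower the difference from untreated larvae. A two-sided exact permutation test of the 12 terpenoid libraries against the 3 untreated ones gave a difference of 1.97 with exact p = 0.0593 over 455 splits. Camera called the list in each of the 4 comparisons (adjusted p = 3.13e-16, 3.07e-10, 8.07e-05 and 6.22e-25) and in none with an estimated correlation (adjusted p = 0.498, 0.556, 0.798 and 0.363 with an estimated correlation).

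**Figure D3:**
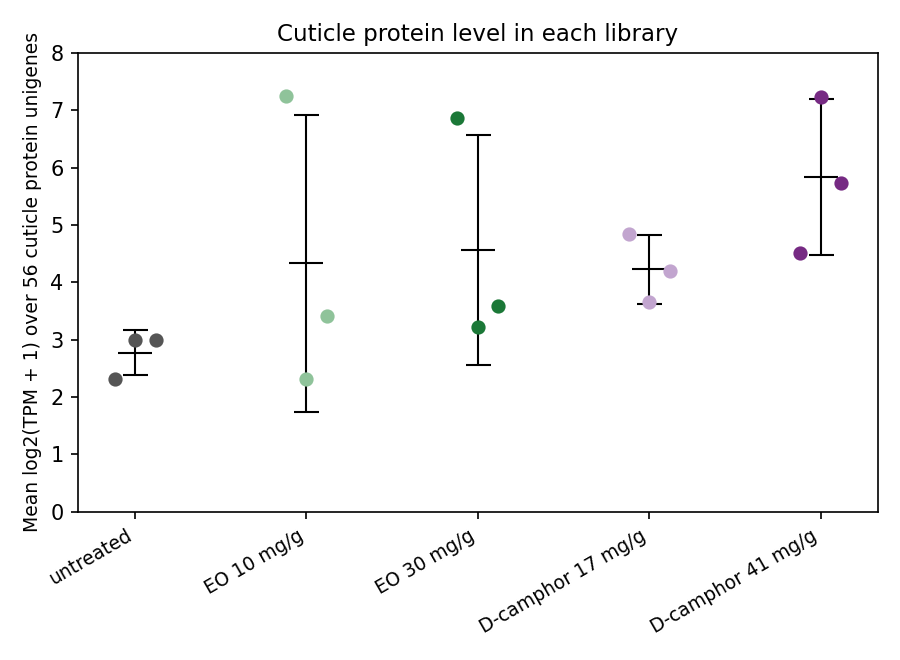
Mean log2(TPM + 1) over 56 cuticle protein unigenes in each of the 15 libraries. Points are single libraries (n = 3 per group), lines and bars are the group mean and SD, and the 3 highest libraries stand at 7.25, 7.23 and 6.87 against 2.32 to 2.99 in untreated larvae.

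The list of moulting and juvenile hormone genes and the list of sulfotransferases and epoxide hydrolases share 11 members, all of them described as juvenile hormone epoxide hydrolases. On EO at 30 mg/g 23 of 26 and 12 of 15 members lay above 0, with medians of 0.66 and 0.98, and the one called member of both is TRINITY_DN1820_c1_g1. Adjusted over the list alone, 6 and 5 members rose. A second epoxide hydrolase (TRINITY_DN26755_c0_g1), chosen after its values were seen, stood at 102 ± 27.3 TPM in untreated larvae and 434 ± 33.9 TPM on EO at 30 mg/g (log2 fold change 2.10, adjusted p = 0.0821 by limma). Camera called both lists in all 4 comparisons with untreated larvae, at adjusted p = 1.04e-09 and 7.84e-07 on EO at 30 mg/g, and lost both in all 4 with an estimated correlation (adjusted p = 0.289, 0.289, 0.499 and 0.707 with an estimated correlation for the first list, on EO at 10 and 30 mg/g and D-camphor at 17 and 41 mg/g). For the second list these were 0.289, 0.289, 0.52 and 0.577. On D-camphor at 41 mg/g the medians were 0.17 and 0.47. In all 15 libraries, 14 of the 26 moulting and juvenile hormone unigenes had a negative within-group correlation with the cuticle mean at an adjusted exact p under 0.05, and 2 a positive one. Without the 3 libraries that lie apart on the first principal component the 14 correlations were between -0.51 and -0.01, so correlations as strong are not shown without these 3. The 3 also have the highest cuticle means, and leaving them out narrows the range, which can weaken a correlation by itself.

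The remaining detoxification lists had 0 members called over all unigenes in the comparisons with untreated larvae. Of 16 glutathione S-transferases, enzymes that join glutathione to foreign compounds, 11 lay above 0 on EO at 30 mg/g (median 0.12), 0 were called by limma over all unigenes, and 5 rose when adjusted over the list alone. The highest estimate in the list was that of TRINITY_DN5815_c0_g1, named after its values were seen, at 254 ± 66.9 TPM in untreated larvae and 654 ± 284 TPM on EO at 30 mg/g (log2 fold change 1.29). Camera called the list on EO at 30 mg/g (adjusted p = 0.000862; adjusted p = 0.289 with an estimated correlation). Of 14 UDP-glycosyltransferases, 10 lay below 0 on D-camphor at 17 mg/g (median -0.21; camera adjusted p = 0.0139; adjusted p = 0.38 with an estimated correlation). Of 14 antioxidant genes, 2 rose on EO at 30 mg/g when adjusted over the list alone, and the list had camera adjusted p = 0.0273 (adjusted p = 0.406 with an estimated correlation). Among 24 carboxylesterases and 40 ABC transporters, 0 members were called by limma in any comparison, and the lowest camera adjusted p values were 0.0756 and 0.0753.

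Lists of digestion and housekeeping gave small medians. Of 80 digestive proteases, 56 lay below 0 on D-camphor at 17 mg/g and 54 at 41 mg/g, with medians of -0.14 and -0.17 (camera adjusted p = 0.000497 and 0.00269; adjusted p = 0.52 and 0.584 with an estimated correlation), and 2 fell at 41 mg/g when adjusted over the list alone. Of 113 cytosolic ribosomal proteins, 77 and 85 lay below 0 on D-camphor at 17 and 41 mg/g, with medians of -0.07 and -0.10 (camera adjusted p = 0.00716 and 0.00136; adjusted p = 0.815 and 0.798 with an estimated correlation). Of 54 oxidative phosphorylation genes, 41 lay above 0 on EO at 30 mg/g, with a median of 0.21 (camera adjusted p = 3.04e-07; adjusted p = 0.501 with an estimated correlation). On EO at 10 mg/g that list had a median of 0.03 (0.18 with scaling) and a mean of -0.12, of opposite sign, while camera set it above the other unigenes (adjusted p = 0.0375; adjusted p = 0.815 with an estimated correlation). Of 18 plant cell wall degradation genes, 13 lay lower on EO at 30 mg/g than at 10 mg/g (median -0.17; camera adjusted p = 4.72e-05; adjusted p = 0.305 with an estimated correlation). Against untreated larvae, 12 of the 18 lay above 0 on EO at 10 mg/g (median 0.08, or 0.23 with scaling; camera adjusted p = 0.0106; adjusted p = 0.502 with an estimated correlation), and the list was not called on EO at 30 mg/g (adjusted p = 0.458). Camera also set it higher on EO at 10 mg/g than on D-camphor at 17 mg/g (median 0.10, or 0.29 with scaling; adjusted p = 0.00146; adjusted p = 0.407 with an estimated correlation). Of 11 chemosensory genes, 9 lay higher on EO at 30 mg/g than on D-camphor at 41 mg/g (median 0.66; camera adjusted p = 0.0216; adjusted p = 0.305 with an estimated correlation).

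The lists of ABC transporters, carboxylesterases, chitin metabolism (14 tested), heat shock proteins (20), immune genes (8), lipid metabolism (31) and muscle (37) were the 7 that camera called in none of the 10 comparisons, with a lowest adjusted p of 0.0753. In total camera called 54 of the 190 tests of lists with the preset correlation and 0 with an estimated correlation, fry called 1 in a direction and 17 in either direction. The fat body, haemocyte, nervous system and germ line lists had 4, 2, 3 and 2 tested members, too few for a list test, and limma called 0 of these members. The list of genes of other organisms matched 0 unigenes.

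The test of any difference among the 5 groups called 9 unigenes by limma's F statistic, and 15 without D-camphor 41 mg/g replicate 1. With all libraries, 1105 (8.83%) had an unadjusted p under 0.05. The step from lower to higher dose was compared between the additives as an interaction. For this limma called 0 unigenes, 1 with a pseudocount of 0.1 and 2 without a filter, and 1448 (11.6%) had an unadjusted p under 0.05. The count was 5 without D-camphor 41 mg/g replicate 1 and 1 without D-camphor 17 mg/g replicate 1. The median over all unigenes was 0.12 and moved by -0.139 with scaling. Probable P450 6a14 (TRINITY_DN1085_c0_g1) had an interaction of 1.57 (SE 0.49, adjusted p = 0.264).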

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

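The comparison of the dose steps was planned, while the tests on moult stage, on 3 libraries alone, on scaling and on shared reads were chosen, and the reading of the splits of the samples was written down, only after the results were seen. The step from the lower to the higher dose differed between the additives for 2 gene lists by camera with the preset correlation. Cuticle protein unigenes had a smaller step on EO than on D-camphor, with 37 of 56 members below 0 and a median difference of -1.16 (adjusted p = 0.000291; adjusted p = 0.798 with an estimated correlation). Oxidative phosphorylation unigenes had a larger step on EO, with 44 of 54 members above 0 and a median of 0.36, or 0.18 with median-of-ratios scaling (adjusted p = 6e-04; adjusted p = 0.689 with an estimated correlation). Limma called 0 single unigenes for this difference, with 1448 (11.6%) at an unadjusted p under 0.05.

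Most cuticle protein estimates lay above 0 on the terpenoid diets, unevenly between libraries, with 0 members called by limma against untreated larvae and exact p = 0.0593 for the mean level. Scaling of the TPM values as the whole cause is argued against by the medians after median-of-ratios scaling, of which the lowest over the 4 diets is 0.83. Whether 3 libraries alone carry the difference over all diets stays open, since the 9 remaining terpenoid libraries stood 1.17 log2 units above the 3 untreated ones with exact p = 0.0864 over 220 splits. The 3 left out are the terpenoid libraries with the highest cuticle means, so a smaller difference was fixed in advance. On EO the difference rests largely on replicate 1 of each dose: without the 3 libraries the medians were 0.2 and 0.4 at 10 and 30 mg/g, against 1.65 and 1.58 with them. On D-camphor at 17 and 41 mg/g they were 0.87 and 2.35, against 0.87 and 3.26. A candidate explanation of the unevenness is a moult stage differing between libraries. The 5 unigenes whose descriptions name ecdysone, FTZ-F1 or a hormone receptor had a mean absolute within-group correlation with the cuticle mean of 0.75. They include HR96, whose part in moulting was not examined. The median was 0.37 in 10000 random lists matched on level, and 0.01 percent of the lists were as high, the smallest share they can give. Members of the random lists were drawn independently, so the share does not allow for unigenes that vary together. It does not measure the spread between libraries either. Without the 3 libraries that lie apart on the first principal component, the 5 correlations were 0.41, 0.34, -0.04, -0.09 and -0.46, so this support depends on those libraries. An effect of the diet on cuticle proteins, the biological explanation that the series title names, cannot be separated from larvae being caught at different stages, because no label gives the stage of each library.

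For the rise of 4 cytochrome P450 family 6 unigenes, scaling as the whole cause is argued against, since the lowest of their log2 fold changes on EO at 30 mg/g after median-of-ratios scaling was 4.83. If the rises of the 3 unigenes near 0 in untreated larvae were reads of 1 induced unigene, their ratios would be equal in the 4 diets, and those of TRINITY_DN9219_c0_g1 to the other 2 were not (highest adjusted exact p = 0.0423). Whether TRINITY_DN12993_c0_g1 and TRINITY_DN32261_c0_g1 rose separately or share reads cannot be told apart (adjusted exact p = 0.234). TRINITY_DN1085_c0_g1 has a level of its own in untreated larvae, so ratios of the rises were used, each at the untreated values that give the highest p: they differed between diets for TRINITY_DN12993_c0_g1 and TRINITY_DN32261_c0_g1 (adjusted exact p = 0.0336 for each), and for TRINITY_DN9219_c0_g1 sharing stays open (adjusted exact p = 0.137). Shared reads would lower the number of induced unigenes and still need at least 1.

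The number of calls in each comparison was set beside other splits of the same libraries. With 3 libraries against 3 there are 10 splits, which cannot give a share under 0.05. As many calls as the real split, itself included, came from 1 split for EO at 10 mg/g (9 calls, highest other 7), 1 for EO at 30 mg/g (23, highest other 4), 2 for D-camphor at 17 mg/g (5, highest other 29) and 1 for D-camphor at 41 mg/g (2, highest other 1). The counts were 2 for EO at 30 against 10 mg/g (1 call, highest other 1), 10 for D-camphor at 41 against 17 mg/g (0 calls, which every split reaches whatever the data, highest other 1), 1 for EO at 10 mg/g against D-camphor at 17 mg/g (1 call, highest other 0) and 1 for EO at 30 mg/g against D-camphor at 41 mg/g (13 calls, highest other 1).

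For the mean of the 4 diets, 2 of 100 drawn splits gave as many as the real 11 calls, the real split included, a share under 0.05. The highest other gave 29 calls (untreated replicate 2 with D-camphor 41 mg/g replicates 1 and 2), more than the real split. Leaving out 1 library moved the real count between 7 and 26. Chance is therefore not excluded by this share. For the F test 8 of 100 gave at least the real 9 calls, so chance is not excluded. For the difference between the dose steps the real count is 0, which all 100 splits reach whatever the data, so the splits say nothing about it (highest other 98). Splits that called 29, 98 and 84 unigenes point to a structure of the libraries, and what the splits with 98 and 84 calls follow was not examined. The split with 29 calls in the D-camphor 17 mg/g comparison sets untreated replicate 1 with D-camphor 17 mg/g replicates 1 and 3, and it follows the second principal component, which holds 22.1% of the variance and on which untreated replicate 1 lies at -35.5 and untreated replicates 2 and 3 at 43 and 30.4.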

How the results depend on the processing

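Of 92 fold changes of named unigenes, 86, 86, 78 and 76 kept their side of the threshold with no filter, a pseudocount of 0.1, median-of-ratios scaling and a block for the replicate number, and 75 and 84 with the 3 libraries highest on the first principal component left out and with the cuticle level as covariate, the 2 settings added after the data were seen. With a filter at 5 TPM 80 of them have a value, of which 78 kept their side. None with a value changed direction. In the order EO 10, EO 30, D-camphor 17 and 41 mg/g against untreated, mean of the diets, EO 30 against 10 mg/g, D-camphor 41 against 17 mg/g, EO 10 mg/g against D-camphor 17 mg/g, EO 30 mg/g against D-camphor 41 mg/g, difference of the dose steps and F test, the calls without a filter were 42, 55, 48, 50, 83, 5, 10, 6, 22, 2 and 51. Leaving out 1 library gave 4 to 10, 8 to 26, 1 to 8, 1 to 11, 7 to 26, 1 to 5, 0 to 9, 1 to 2, 9 to 21, 0 to 5 and 8 to 15. Other settings are given where they moved a count over 1.5 times. A pseudocount of 0.1 gave 5 (D-camphor 41 mg/g), 2 (EO doses), 2 (lower doses of EO and D-camphor), 1 (dose steps) and 15 (F test). A filter at 5 TPM gave 11 (D-camphor 17 mg/g) and 15 (F test). Median-of-ratios scaling gave 13 (EO 30 mg/g), 5 (D-camphor 41 mg/g) and 17 (mean of the diets). Array quality weights gave 60 and 20 (D-camphor 17 and 41 mg/g), 32 (mean), 46 (D-camphor doses), 9 (lower doses) and 63 (F test). The groups compared alone gave 1 (EO 10 mg/g), 25 and 0 (D-camphor 17 and 41 mg/g), 0 (EO doses), 16 (D-camphor doses), 0 (lower doses), 4 (higher doses) and 1 (dose steps), from fewer libraries. Without the 3 libraries there were 5 (D-camphor 41 mg/g), 23 (mean), 0 (EO doses), 0 (lower doses) and 3 (higher doses), and with the covariate 48 (EO 30 mg/g) and 24 (mean). The replicate block gave 12 (EO 30 mg/g) and 1 (D-camphor 17 mg/g). No pairing by replicate number was detected, since residuals of the same number had a median correlation of 0.02 and those of other numbers 0.02. The highest were 0.56 and 0.44, and a pairing in part of the groups is not excluded. Of the 54 called list tests, 52 were called with the block (lost: moulting and juvenile hormone on D-camphor 41 mg/g, adjusted p = 0.0781, and cuticle protein at the higher doses, 0.0723), 1 by fry and 0 with an estimated correlation. Fry set 5 the other way: oxidative phosphorylation on EO 10 mg/g (adjusted p = 0.971) and, at the lower doses of EO and D-camphor, P450 (0.927), digestive protease (0.866), moulting and juvenile hormone (0.995) and ribosomal protein (0.961). The cause was not tested where none is given. TPM gives no depth, so what depth limits is unknown.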

Other observations

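Pulses of ecdysone time insect moults. Of 5 tested unigenes whose descriptions name ecdysone, FTZ-F1 or a hormone receptor, 2 were higher and 1 lower in libraries with high cuticle protein levels. HR96 entered by its description as a hormone receptor, and its part in moulting was not examined. All tests in this part were chosen after the results were seen. The nuclear receptor FTZ-F1 (TRINITY_DN1032_c0_g1), which acts after the ecdysone peak in insects, stood at 12.13 TPM in EO 10 mg/g replicate 1, 8.22 in D-camphor 41 mg/g replicate 2 and 3.71 in EO 30 mg/g replicate 1, against 1.11, 0.66 and 0.68 in untreated larvae. Its correlation with the cuticle mean within groups was 0.90 (15 libraries, exact p = 0.0129 over 7776 arrangements, adjusted over 26 relations 0.028), and the rank correlation 0.80 (exact p = 0.022). Ecdysone-induced protein 74EF (TRINITY_DN6767_c0_g1) had 0.92 (adjusted exact p = 0.0217) and ecdysone 20-monooxygenase (TRINITY_DN22851_c0_g1), the enzyme that makes the active hormone, -0.92 (adjusted exact p = 0.0217). Without the 3 libraries with the highest cuticle levels the correlations were 0.34, 0.41 and -0.46, so a relation as strong is not shown without these 3. Leaving out the highest levels narrows their range, which can weaken a correlation by itself. With all libraries, HR96 (0.66, adjusted exact p = 0.123) and HR4 (-0.33, adjusted exact p = 0.216) did not pass.

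The 7 tested unigenes described as the uncharacterized proteins LOC109542840, LOC109542841 or LOC109542842, grouped by these descriptions after the falls on EO at 30 mg/g were seen, summed to 20700 ± 5020 TPM in untreated larvae, 16300 ± 3310 and 7750 ± 1140 TPM on EO at 10 and 30 mg/g, and 14100 ± 1410 and 11700 ± 2110 TPM on D-camphor at 17 and 41 mg/g (SD, n = 3). All 7 had estimates below 0 on EO at 30 mg/g, and 5 were among its 10 falls, which ended as calls with median-of-ratios scaling. TRINITY_DN19853_c0_g1 (adjusted p = 0.519 by limma) and TRINITY_DN34156_c1_g1 (adjusted p = 0.0755) did not pass. Whether the 7 are related in sequence was not examined.

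The levels of 3 unigenes, chosen after their values were seen, are given as values alone. Their means over all libraries lie under 1 TPM, so the main limma fit, which has a filter at 1 TPM, tested none of them. A flocculation protein FLO5-like unigene (TRINITY_DN25180_c0_g1) stood at 3.24 ± 2.17 TPM in untreated larvae (n = 3) and 0.122 ± 0.257 TPM on the 4 terpenoid diets (n = 12). A pleiotropic ABC efflux transporter (TRINITY_DN18260_c0_g1) stood at 2.14 ± 0.76 and 0.249 ± 0.164 TPM, and a plasma membrane ATPase-like unigene (TRINITY_DN22214_c0_g3) at 0.667 ± 0.466 TPM and 0 in all 12. The descriptions name proteins known from yeasts, but no list of fungal genes was tested.

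Transcripts of another organism, such as a microbe that the terpenoids hold back, are a candidate explanation of low-level unigenes highest in untreated larvae, and this stays open. The test does not address the 3 unigenes above, whose matched entries are flies and so fall in its comparison class. Unigenes described from animals other than arthropods were highest in all 3 untreated libraries for 26 of 1028, against 69 of 16499 described from arthropods, an odds ratio of 6.18 (95% interval 3.76 to 9.88, Fisher's exact p = 2.1e-11), where chance gives 0.22%. The odds ratio was 5.7 among unigenes with a mean of at least 0.5 TPM (exact p = 0.00756) and 4.55 at 1 TPM (exact p = 0.0804), and between 0 and 0.417 for the other 4 groups at 0.1 TPM. On D-camphor at 17 mg/g it was 0.996 at 0.5 TPM and 1.38 at 1 TPM, where 3 of 171 were highest, against 2 of 171 in untreated larvae, so at 1 TPM the excess is not shown to be confined to untreated larvae. Unigenes are not independent replicates, and a change in the larva's own distant genes stays open. The organism cannot be named from these descriptions.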
